A study of Mus musculus with 21 samples.

How the data were processed

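RNA-seq was run on bone marrow-derived macrophages of C57Bl6/J mice, grown in RPMI-1640 with L929-conditioned medium, a usual source of the growth factor that turns marrow cells into macrophages. Per the labels' protocols, marrow donors were fed standard chow or a Western diet rich in fat, sugar and cholesterol for 24 weeks. Some chow cultures were grown for the first 4 days in fatty acid at 10 mM, with palmitic to oleic acid at 1:3, with or without 200 nM TAK242, an inhibitor of the lipopolysaccharide (LPS) receptor TLR4. On day 7, cultures assigned to stimulation received 100 ng/ml LPS for 24 h. The 21 libraries form 7 groups of 3, and the labels give replicate numbers without saying whether a number stands for an animal or a culture.

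The values come as a fatty acid table of 12 libraries and a Western diet table of 9 libraries. Per the submitters' processing notes, CASAVA 1.8.2, FastQC 0.11.5, Trim Galore 0.4.1 and HISAT2 2.0.5 were used, and builds mm10 and mm9 are both named without their roles. Neither the notes nor the file headers name the quantification step or the unit. The deposited values, written with decimal commas, behave like FPKM: low values of single-exon genes step with gene length, and library sums run from 321532 to 386023. The unit is therefore given as the deposited value, in place of a named unit, and the authors' normalization beyond it is unknown. Gene coordinates equal those of GRCm38 GENCODE M21 exactly in 46773 of 50645 genes of the fatty acid table and 46772 of 50644 of the Western diet table. A reference name table paired 50336 and 50335 of the gene IDs with symbols. Entries with numbers displaced into annotation columns were left out (36 entries of 17 gene IDs in the fatty acid table, 35 of 18 in the Western diet table).

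Read counts were not used here. The smallest steps of single-exon genes imply a depth of 17.8 to 35.7 fragments in units of 1e6 per library, an estimate that rests on few values per library. Between 8803 and 10145 genes had a value of at least 1, and the most abundant gene took 2.51% to 13.95% of a library's sum.

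Whether the tables share a normalization is unknown, so every fit stayed within a table. The count test chosen at the outset did not apply to this unit, and the route for normalized values was used in its place. Genes with a value of at least 1 in 3 or more libraries of a table were kept (10476 and 10331 genes), and log2(value + 1) was fitted with limma 3.58.1 with a mean-variance trend in R 4.3.3. All libraries of a table shared an estimate of spread. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 counted as changed. Every adjusted p of a gene in the text is limma's, except in the LPS response by diet, where it is that of the difference test below. Log2 changes are on the log2(value + 1) scale, which understates changes of genes with low values. The difference between LPS responses in the tables was tested from the standard errors of the separate fits, with Welch-Satterthwaite degrees of freedom, over the 10019 genes in both.

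Lists of genes (35 in all) were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 5 members had been kept, adjusted over the lists of a comparison. Each was also tested with an estimated correlation and with fry, which asks whether members move one way on balance. Fold changes of comparisons that share libraries were compared with 100 simulated draws of unchanged groups. These draws took genes as independent, with the same spread in every group. The genes to name were set by a rule: the 8 largest rises and 8 largest falls past the threshold whose groups do not overlap and whose mean reaches 10 in the higher group, leaving out unnamed gene models. The rule added 2 to 4 members of each list described, by smallest adjusted p, and focal genes of inflammation and lipid handling. For the LPS response by diet it took 5 genes each way. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

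Other settings fixed at the outset were no filter, a minimum of 5, only the 6 libraries compared, a pseudocount of 0.1, leaving out each library, and the replicate number as a block. Median-ratio scaling between libraries, leaving out 4 doubted libraries, the block and pseudocount for the LPS response by diet, and leaving out libraries for the correlations between comparisons were added after seeing the data. When libraries were left out or rescaled, the genes tested were held fixed. That choice was also made after seeing results: in a first version the filter was applied again, which removed genes present in a single group. Data handling and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

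The fit was tested on simulated data with 200 changed genes. For fatty acid pretreatment (10476 genes) it recovered 76% of 2-fold and 96% of 4-fold changes, with 11 false calls among 183. For Western diet without LPS (10331 genes) it recovered 27% and 62%, with 6 false calls among 95. A simulated shift of 1 log2 unit in 1 of the 28 lists tested in the fatty acid table was recovered with 0 false calls. Genes were simulated as independent, so this cannot show false calls from correlated members. The estimated correlation of interferon-stimulated genes, for example, was 0.646. Of 200 simulated differences of 4 log2 units between LPS responses, 195 were recovered, with 18 false calls among 10019 genes.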

Results

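Transcripts were measured in 21 libraries of mouse bone marrow-derived macrophages in 7 groups of 3. The fatty acid table held untreated macrophages of chow-fed mice, the same with LPS, with fatty acid before LPS, and with fatty acid and TAK242 before LPS. The Western diet table held untreated macrophages of chow-fed mice (replicates 4 to 6) and libraries labelled Western diet without and with LPS. Library sums lay between 321532 and 386023 deposited values. Values below are means ± SD with n = 3, and changes are log2 changes.

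The first comparison asks how LPS, a bacterial membrane lipid, alters macrophages of chow-fed mice. The chemokine gene Ccl5 (chromosome 11, 83525778 to 83530518) rose from 0.540 ± 0.114 to 5211 ± 1616, a log2 change of 11.68 with a standard error of 0.29 (adjusted p = 2.86e-10). The acute phase gene Saa3 rose from 7.37 ± 0.739 to 30450 ± 17900 (11.65, adjusted p = 1.46e-08). Acod1, which encodes the enzyme that makes itaconate, rose from 0.449 ± 0.0522 to 348.1 ± 27.5 (7.91, adjusted p = 3.11e-11). The mitotic cyclin gene Ccnb2 fell from 63.3 ± 4.00 to 0.367 ± 0.0848, a change of -5.56 (adjusted p = 3.11e-11). The mannose receptor gene Mrc1 fell from 294.3 ± 37.8 to 6.12 ± 2.29, a change of -5.42 (adjusted p = 5.39e-09).

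Of 10476 genes tested, 6463 changed with LPS, 1444 upward and 5019 downward, and at least 2-fold changes numbered 638 and 1447. The median of all genes stood at -0.31, and median-ratio scaling moved it by 0.30. After that scaling 5668 genes changed, 2746 upward and 2922 downward, so the share of higher calls went from 22.3% to 48.4%, and 363 of the calls changed sign. With each of the 6 libraries left out in turn, 5364 calls kept their direction and stayed past the threshold, as did all 51 named genes that had changed. Applying the filter again in those fits left 4901.

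Among lists fixed beforehand, 36 of 37 interferon-stimulated genes rose and 0 fell (37 rose when adjusted over the list alone; camera adjusted p = 8.48e-33, adjusted p = 0.0923 with an estimated correlation). Zbp1 went from 1.38 ± 0.225 to 145.0 ± 39.9, and Irf7 from 1.04 ± 0.130 to 255.0 ± 111.2. All 17 members of the class I and immunoproteasome list rose, 17 also adjusted over the list alone (adjusted p = 2.21e-14; adjusted p = 0.137 with an estimated correlation). Of 17 chemokine genes 15 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 3.07e-09; adjusted p = 0.0163 with an estimated correlation), and this was the list that held with an estimated correlation. Of 13 inflammatory cytokine genes 11 rose, 11 adjusted over the list alone (adjusted p = 3.52e-08; adjusted p = 0.0580 with an estimated correlation). Il1b rose by 9.17 with widely spread values of 930.8 ± 925.6, and Il6 by 3.76 with 18.5 ± 19.2.

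The cell cycle list fell in 28 of 29 members, 28 adjusted over the list alone (adjusted p = 3.25e-11; adjusted p = 0.187 with an estimated correlation), and the cholesterol synthesis list in 22 of 24, 22 adjusted over the list alone (adjusted p = 8.70e-06; adjusted p = 0.105 with an estimated correlation). Cyp51 fell by 2.03 and Hmgcs1 by a change of -1.62. These counts were 28 and 21 after scaling. Respiratory chain genes depended on scaling, with 3 higher and 10 lower before it and 6 higher and 3 lower after it, and ER stress genes went from 4 higher and 5 lower to 10 higher and 1 lower. Markers of stromal cells rose in 7 of 8 members, 7 adjusted over the list alone (adjusted p = 0.000201; adjusted p = 0.213 with an estimated correlation), with Col1a1 at 5.78 ± 3.71 against 1.47 ± 0.510. Markers of neutrophils rose in 3 of 6 with 0 lower, 3 adjusted over the list alone (adjusted p = 0.00560; adjusted p = 0.0868 with an estimated correlation). Nos2 was listed at 0 in the 3 controls and at 4.38, 9.57 and 17.3 with LPS. Mrnip, with a change of -5.56, overlaps the abundant Sqstm1, so its values are uncertain.

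**Figure D1:**
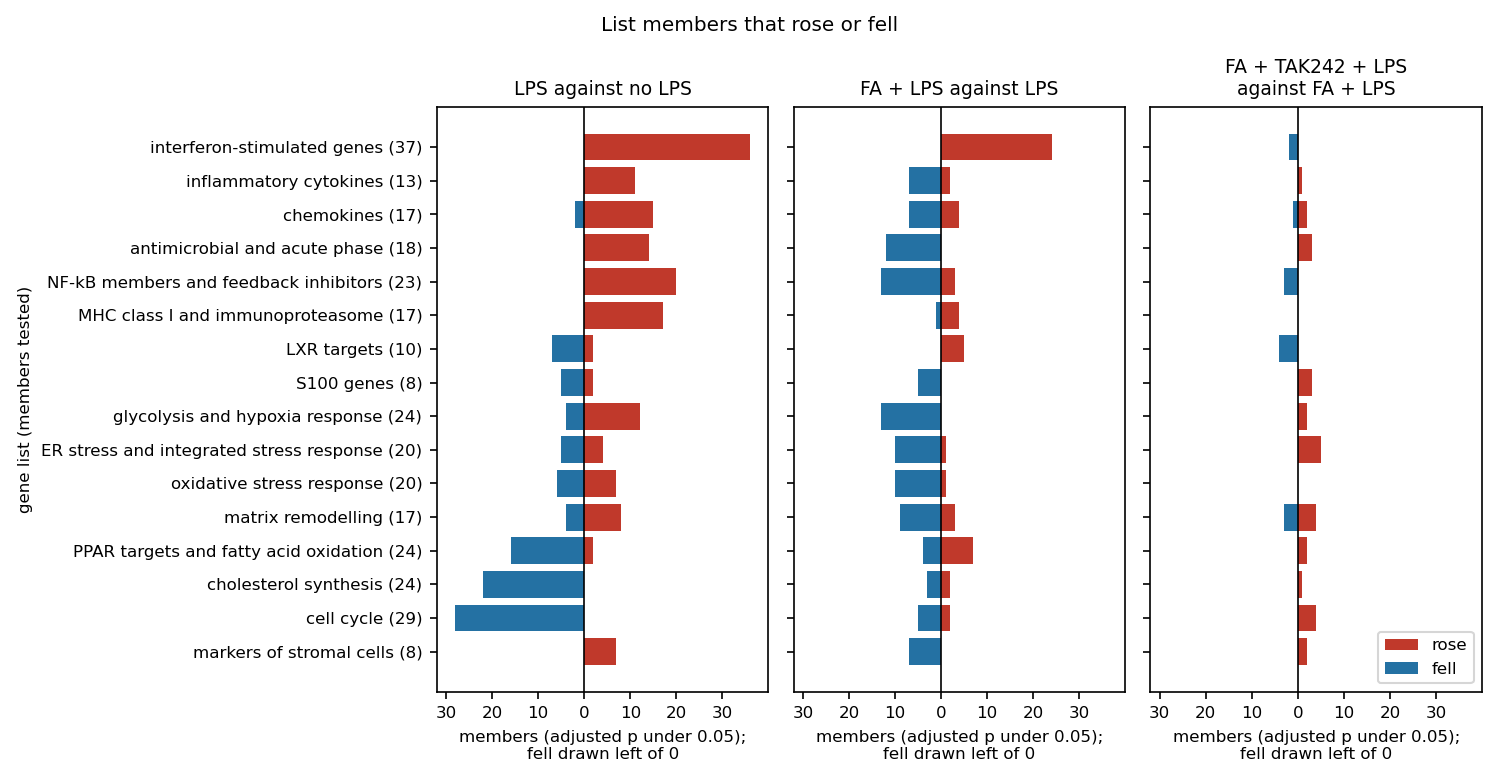
Bars give the number of list members (members tested in brackets) that rose or fell at an adjusted p under 0.05 for LPS, for fatty acid before LPS, and for TAK242 added to fatty acid, with falls drawn left of 0. With LPS 36 of 37 interferon-stimulated genes rose, and with fatty acid 24 of the 37 were higher than with LPS alone; directions of the respiratory chain list, not drawn, and of the ER stress list with LPS change under median-ratio scaling.

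The next comparison sets fatty acid before LPS against LPS alone. No group had fatty acid without LPS. A change of the LPS response therefore cannot be separated from an effect that fatty acid has without LPS. The neutrophil-attracting chemokine genes Cxcl3 and Cxcl2 fell most. Cxcl3 stood at 553.6 ± 847.2 with LPS alone and 1.09 ± 0.0587 with fatty acid (-6.32, standard error 1.07, adjusted p = 0.00179), against 0.136, 0.0216 and 0.1497 in the untreated libraries. Il1b, which encodes interleukin 1 beta, fell from 930.8 ± 925.6 to 34.7 ± 9.13 (-4.23, adjusted p = 0.000941). The macrophage lipid-binding gene Cd5l rose from 2.05 ± 0.892 to 24.7 ± 0.554 (3.12, adjusted p = 3.31e-05), and the chemokine gene Ccl8 from 3.72 ± 3.28 to 35.9 ± 1.85 (3.21, adjusted p = 0.000556). The antiviral gene Ifit2 rose from 7.37 ± 5.56 to 49.5 ± 3.62 (2.84, adjusted p = 0.000801).

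Fatty acid changed 3893 of 10476 genes, 2286 upward and 1607 downward, of which 303 and 295 by at least 2-fold. After median-ratio scaling 2084 were higher and 2076 lower, so no excess of either direction is given. Of the calls, 2470 held with each of the 6 libraries left out in turn (2426 with the filter applied again), as did 51 of the 53 named genes that had changed. The exceptions were Cd36 (adjusted p = 0.0503 without fatty acid replicate 2) and S100a8 (adjusted p from 0.0664 to 0.0793 without fatty acid replicate 1, 2 or 3). LPS replicate 1 stood apart, with Il1b at 1987 against 543.2 and 262.1 and Cxcl3 at 1531 against 101.8 and 28.2. Without it the change of Slpi went from -3.77 to -2.5, that of Cxcl1 from -3.64 to -2.04, that of Cxcl10 from 1.58 to 1.05, that of Cd36 from -0.80 to -0.46 and that of S100a8 from -1.34 to -0.69. The call of Cxcl1 was lost without a filter (adjusted p = 0.0568) and with only the 6 libraries compared (adjusted p = 0.0827).

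Interferon-stimulated genes were higher with fatty acid, 24 of 37 with 0 lower and 27 adjusted over the list alone (camera adjusted p = 3.59e-06; adjusted p = 0.503 with an estimated correlation). Among them Mx1 went from 31.7 ± 20.9 to 175.1 ± 46.0 and Iigp1 from 0.639 ± 0.614 to 4.58 ± 0.415. LXR targets, genes of cholesterol export, rose in 5 of 10 members, 7 adjusted over the list alone (adjusted p = 0.000805; adjusted p = 0.342 with an estimated correlation). Apoe went from 641.2 ± 103.8 to 1779 ± 230.1, Abcg1 from 4.43 ± 0.928 to 17.5 ± 0.795, and Pltp, which overlaps Ctsa, from 18.0 ± 5.02 to 100.3 ± 6.23.

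Antimicrobial and acute phase genes fell in 12 of 18 members, 12 adjusted over the list alone (adjusted p = 4.01e-06; adjusted p = 0.342 with an estimated correlation). Of 13 inflammatory cytokine genes 7 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.00268; adjusted p = 0.342 with an estimated correlation); Il6 went from 18.5 ± 19.2 to 0.277 ± 0.168, Tnf from 55.8 ± 39.7 to 14.1 ± 3.36 and Il12b from 2.89 ± 0.949 to 0.168 ± 0.0497. S100 genes fell in 5 of 8, 6 adjusted over the list alone (adjusted p = 0.00116; adjusted p = 0.342 with an estimated correlation), with S100a4, whose values are uncertain because it overlaps Gm42674, from 110.7 ± 9.10 to 26.9 ± 4.48. Glycolysis and hypoxia genes fell in 13 of 24 (13 adjusted over the list alone) and ER stress genes in 10 of 20 with 1 higher (10 and 1 adjusted over the list alone). Their adjusted p values were 0.000646 and 0.000714, with adjusted p = 0.371 with an estimated correlation for glycolysis and adjusted p = 0.342 with an estimated correlation for ER stress. Stromal markers moved with these falling groups, 7 of 8 lower (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.000784; adjusted p = 0.371 with an estimated correlation), and Col1a1 went from 5.78 ± 3.71 to 0.661 ± 0.123. Il10, Ccl2, Plin2, Nos2, Abca1 and S100a9 did not pass the threshold. Without LPS replicate 1, Ccl2 passed at -0.69 (adjusted p = 0.0347) and S100a9 at -0.77 (adjusted p = 0.0288), and without LPS replicate 3 Nos2 passed at 1.04 (adjusted p = 0.0155). Cd14 fell by 2.37 and Tlr4, the LPS receptor gene, rose by 0.49 (adjusted p = 0.000598 and 0.00148).

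TAK242 with fatty acid was compared with fatty acid alone, both before LPS. With no group of TAK242 without fatty acid, an effect on the fatty acid change cannot be separated from an effect on the later LPS response. Mmp12, a macrophage elastase gene, rose from 14.7 ± 3.35 to 85.8 ± 20.1 (2.46, standard error 0.36, adjusted p = 0.00693), and the collagen gene Col18a1 from 2.58 ± 0.352 to 12.6 ± 0.802 (1.93, adjusted p = 0.000177). Pf4, a chemokine gene of platelets and macrophages, rose from 287.6 ± 43.7 to 948.3 ± 71.2 (1.73, adjusted p = 0.00124). Cd5l fell from 24.7 ± 0.554 to 5.07 ± 1.39 (-2.11, adjusted p = 0.00098), and Apoe, the apolipoprotein E gene, from 1779 ± 230.1 to 660.7 ± 104.1 (-1.43, adjusted p = 0.00165). Raver2 fell as well, but it overlaps Jak1, its values jump between libraries, and its call was lost without each of the 6 libraries in turn (adjusted p from 0.0727 to 0.131).

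TAK242 changed 491 genes, 315 upward and 176 downward, with 43 and 28 by at least 2-fold. The number rested on single libraries: it was 305, 91 and 66 without fatty acid replicate 1, 2 or 3, and 114, 63 and 297 without TAK242 replicate 1, 2 or 3. It was also 276 without a filter, 1110 with only the 6 libraries compared and 751 after median-ratio scaling. With each of the 6 libraries left out in turn 52 calls held, and 12 of the 37 named genes that had changed: Mmp12, Col18a1, Pf4, Serf1, Cd5l, Apoe, Il12b, S100a4, Apoc1, Mmp14, Mmp13 and Timp2. LXR targets fell in 4 of 10 members, 4 adjusted over the list alone (camera adjusted p = 0.000182; adjusted p = 0.331 with an estimated correlation), and S100 genes rose in 3 of 8, 3 adjusted over the list alone (adjusted p = 0.00800; adjusted p = 0.372 with an estimated correlation). Glycolysis and hypoxia genes rose in 2 of 24, and in 14 adjusted over the list alone (adjusted p = 2.01e-06; adjusted p = 0.372 with an estimated correlation), while 2 of 37 interferon-stimulated genes fell, 3 adjusted over the list alone (adjusted p = 8.92e-05; adjusted p = 0.698 with an estimated correlation). Il1b, at 161.9 ± 91.4 against 34.7 ± 9.13, did not pass (adjusted p = 0.0840), and Tnf did not either (16.4 ± 4.28 against 14.1 ± 3.36, adjusted p = 0.799).

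**Figure D2:**
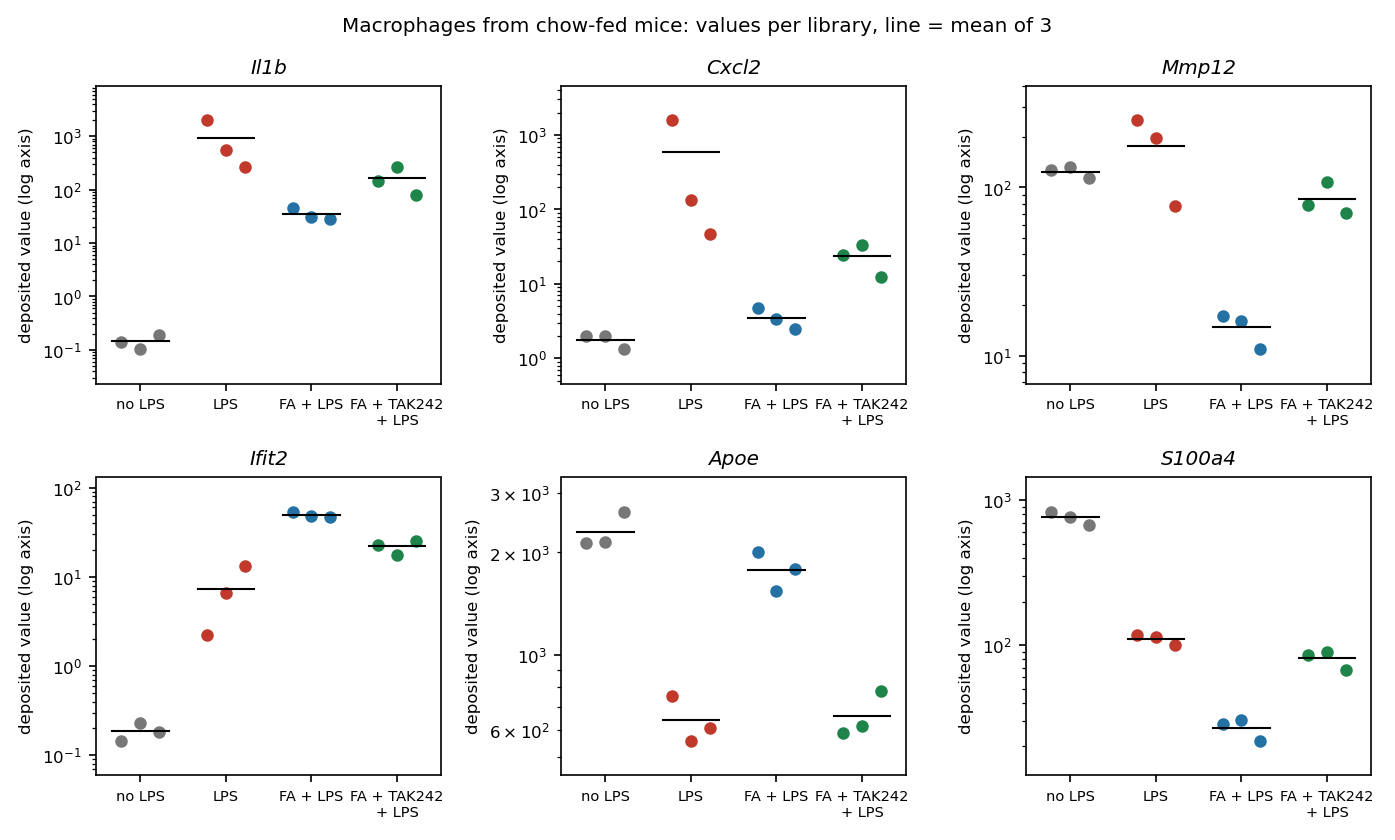
Points are deposited values of single libraries of chow macrophages on a log axis, for Il1b, Cxcl2, Mmp12, Ifit2, Apoe and S100a4 (which overlaps Gm42674), and lines are means of 3. Apoe had a mean of 641.2 with LPS, 1779 with fatty acid and 660.7 with TAK242 added.

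The fatty acid and TAK242 changes were set side by side because they share the fatty acid libraries, which alone gives a negative relation. Across 10476 genes, which are not independent replicates, their correlation was -0.766 against -0.504 simulated with no effect. The covariance was -0.135 against -0.0222, a difference of -0.113. Signs were opposite in 78.7% of genes, against 66.7% simulated. Of the 2286 genes raised by fatty acid, TAK242 lowered 169 past the threshold (38.4 for independent lists), and of the 1607 lowered genes it raised 245 (48.3 for independent lists); 0 moved further the same way past it. The shared libraries were not split between the comparisons, so part of the excess may come from them.

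Fatty acid with TAK242 was also compared with LPS alone. No group had TAK242 without fatty acid. What is left of the fatty acid change therefore cannot be separated from an effect of TAK242 itself on the LPS response. Tnf, the tumor necrosis factor gene, fell from 55.8 ± 39.7 to 16.4 ± 4.28 (-1.51, standard error 0.39, adjusted p = 0.0484). The LPS co-receptor gene Cd14 fell from 105.0 ± 48.7 to 39.3 ± 12.9 (-1.34, adjusted p = 0.0379), and Ifit2 rose from 7.37 ± 5.56 to 21.97 ± 4.11 (1.69, adjusted p = 0.0408). In all 617 genes changed, 424 upward and 193 downward; after median-ratio scaling 1005 changed, 456 upward and 549 downward, so the share of higher calls went from 68.7% to 45.4%. The count was 29, 29 and 1784 without LPS replicate 1, 2 or 3, and 12, 268 and 1 without TAK242 replicate 1, 2 or 3. It was 88 without a filter and 2 with only the 6 libraries compared. Tnf was lost without each library but LPS replicate 3, with adjusted p of 0.0685 and 0.0876 without LPS replicate 1 or 2, and 0.127, 0.0631 and 0.156 without TAK242 replicate 1, 2 or 3; without LPS replicate 1 its change was -0.98. Ifit2 was lost without the same libraries (adjusted p = 0.0584, 0.0872, 0.11, 0.0616 and 0.14; change of 1.12 without LPS replicate 1), and Cd14 without LPS replicate 1 or 2 or TAK242 replicate 1 or 3 (adjusted p = 0.0771, 0.0900, 0.0989 and 0.139). The call that held in all 6 was n-R5s202, a small RNA gene inside Emc7 whose reads cannot be told apart. The antimicrobial list fell in 2 of 18 members, 5 adjusted over the list alone (camera adjusted p = 5.97e-05; adjusted p = 0.465 with an estimated correlation). Stromal markers fell with it, 2 of 8 with 5 lower adjusted over the list alone (adjusted p = 0.00126; adjusted p = 0.465 with an estimated correlation). Mitochondrially encoded transcripts stood lower, 0 of 11 past the threshold and 2 adjusted over the list alone (adjusted p = 0.00126; adjusted p = 0.485 with an estimated correlation). The correlation with the fatty acid changes was 0.820 against 0.496 simulated from the shared LPS libraries, and the covariance 0.162 against 0.0216. The shared LPS libraries were not split between the comparisons. In genes such as Tnf they were more spread than the TAK242 libraries, while the simulated spread was the same in every group. Part of the excess may therefore come from them, and it does not show how much of the fatty acid change was left.

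In the Western diet table the LPS-responsive genes did not follow the labels. Ccl5 stood at 7846, 13.7 and 10970 in the libraries labelled Western diet without LPS (replicates 1, 2 and 3) and at 0.463, 10.5 and 6905 in those labelled with LPS, against 2.06, 2.38 and 1.57 in the chow controls. Across 1975 genes with an LPS change of at least 2-fold in chow macrophages, each library's slope on those changes was 1.01, 0.06 and 1.03 without LPS by label, and -0.11, -0.09 and 0.75 with LPS by label. Directions drawn from these labels are therefore given by label only.

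**Figure D3:**
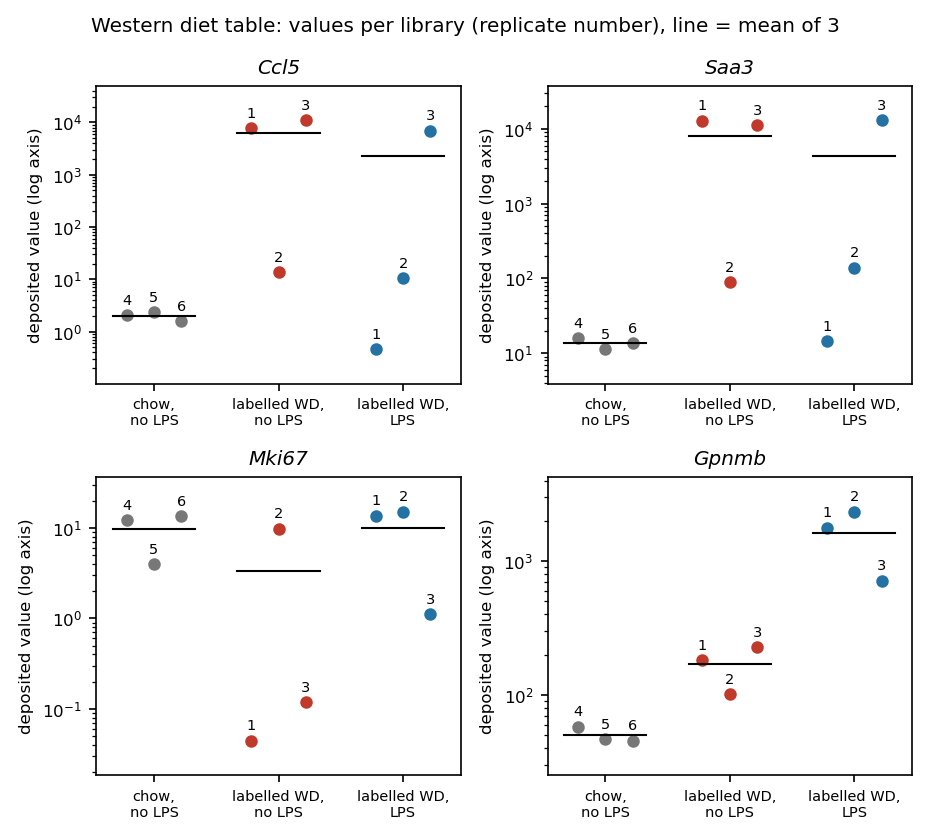
Points are deposited values of single libraries of the Western diet table, numbered by replicate, on a log axis for Ccl5, Saa3, Mki67 and Gpnmb, and lines are means of 3. In Ccl5 and Saa3 replicates 1 and 3 labelled without LPS and replicate 3 labelled with LPS stand high, whereas Gpnmb is higher in all 3 libraries labelled with LPS. Gpnmb was taken from the genes called by label.

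For Western diet without LPS by label against chow, Arg1, the arginase gene of alternative activation, rose from 0.593 ± 0.212 to 40.2 ± 13.2 (4.64, standard error 0.61, adjusted p = 0.0284). Of 10331 genes tested 24 changed, 7 upward and 17 downward, while 2825 had an unadjusted p under 0.05. Leaving out the 4 libraries whose LPS-responsive genes go against their label left a lone library labelled Western diet in this comparison, so no count is read from that fit. In that fit 0 of the 24 calls changed sign. The 24 were called from values that include the libraries left, so this is no independent evidence for them. Of the 24, 5 lie on chromosome X and 4 on chromosome Y: Eif2s3y was listed at 0 in the chow controls and at 15.1, 27.5 and 21.98 in the libraries labelled Western diet, and Tsix was listed at 0 in these and at 14.5, 8.59 and 14.4 in the controls. Overlapping genes were looked for with values of the fatty acid table only, so whether Tsix holds reads of another gene was not judged. The median of all genes stood at -0.32. The count was 8, 12 and 10 without chow replicate 4, 5 or 6, and 10, 5838 and 9 without the library labelled Western diet replicate 1, 2 or 3; 8 calls held in all of these, and 1 with the filter applied again. Arg1 was not among the 8, with adjusted p from 0.145 to 0.205 without chow replicate 4, 5 or 6, and 0.160 and 0.158 without replicate 1 or 3 labelled Western diet. Arg1 was lost without a filter (adjusted p = 0.0592) and after median-ratio scaling (adjusted p = 0.0563), and the count was 41 without a filter and 12 with a minimum of 5. By camera, interferon-stimulated genes stood higher (adjusted p = 1.00e-18; adjusted p = 0.311 with an estimated correlation) and the cell cycle list lower (adjusted p = 2.86e-05; adjusted p = 0.682 with an estimated correlation), with 0 members past the threshold in either, and 0 adjusted over the list alone.

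For LPS against no LPS by label in Western diet libraries, Chil3, a chitinase-like gene, rose from 1.02 ± 0.587 to 18.2 ± 3.47 (3.27, standard error 0.25, adjusted p = 0.00223). Ctse, a protease gene, rose from 0.0224 ± 0.0197 to 23.9 ± 15.3 (4.38, adjusted p = 0.00485), and the inflammasome gene Nlrp3 fell from 24.97 ± 2.71 to 5.31 ± 1.37 (-2.06, adjusted p = 0.00479). In all 99 of 10331 genes changed, 70 upward and 29 downward, with a median of all genes of 0.16, while 1779 had an unadjusted p under 0.05. It was 58 with a minimum of 5, 210 after median-ratio scaling, 2 with only the 6 libraries compared and 0 with the replicate number as a block, so that Chil3, Ctse and Nlrp3 were lost in these last settings. Leaving out the 4 libraries whose LPS-responsive genes go against their label left a lone library per arm, so no count is read from that fit. In that fit 0 of the 99 calls changed sign. The 99 were called from values that include the libraries left, so this is no independent evidence for them. The 4 were chosen by LPS-responsive genes, so a turn of such genes there is built in. The count was 23, 4086 and 21 without the library labelled without LPS replicate 1, 2 or 3, and 24, 18 and 747 without replicate 1, 2 or 3 labelled with LPS. Calls that held in all numbered 17 (8 with the filter applied again), among them Ctse, Mgst2, Chil3, Rapgef5, Nlrp3, St3gal5 and Lbp. Fabp5, a lipid-binding gene, rose from 60.0 ± 14.1 to 1253 ± 726.2 (4.15, adjusted p = 0.0110), and was lost without replicates 1 or 3 labelled without LPS (adjusted p = 0.0551 and 0.0574) or replicates 1 or 2 labelled with LPS (0.0659 and 0.0553). NF-kB members stood lower by camera, with 0 of 22 past the threshold and 5 adjusted over the list alone (adjusted p = 2.12e-12; adjusted p = 0.448 with an estimated correlation). Markers of neutrophils stood higher, 1 of 5 past the threshold and 3 adjusted over the list alone (adjusted p = 0.0171; adjusted p = 0.329 with an estimated correlation).

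The response to LPS by label differed between the diets in 4291 of 10019 genes, 3217 with a higher and 1074 with a lower change in the libraries labelled Western diet. The excess of higher calls rests on scaling and libraries: it was 2161 against 2009 after median-ratio scaling. Leaving out the 4 libraries whose LPS-responsive genes go against their label left a lone library per Western diet arm, so no count is read from that fit. In that fit 686 of the 4291 calls changed sign. The 4 were chosen by LPS-responsive genes, so turns of such genes there are built in. The mitosis gene Stmn1 changed by -5.03 in chow and 3.51 in Western diet libraries, a difference of 8.54 (standard error 1.62, adjusted p = 0.00543), and Ccl5 by 11.68 and -4.47, a difference of -16.14 (standard error 3.37, adjusted p = 0.00774). These Western diet changes average over libraries that differ in LPS state. Without the 4 libraries that of Stmn1 turned to -2.88 and that of Ccl5 to 8.88, with differences from chow of 2.14 and -2.80. With a single Western diet library left out, that of Stmn1 ran from 2.55 to 5.37 and that of Ccl5 from -8.04 to -1.94. The macrophage gene Cd5l kept its direction, at 3.30 and at 1.90 from the lone library per arm left without the 4, against -4.76 in chow. Diet coincides with the table, so they cannot be separated. The count was 2304, 6767 and 2385 without replicate 1, 2 or 3 labelled without LPS, and 2211 and 2142 without replicate 1 or 2 labelled with LPS, and 2731 with a minimum of 5. The correlation of the LPS changes across genes was -0.723 (Spearman -0.628) and turned to 0.664 without those 4 libraries, and that of the chow LPS change with the Western diet change without LPS was 0.757. Fatty acid and Western diet changes had a correlation of 0.216 (Spearman 0.236), and of 0.094 without those libraries; 1 gene rose and 4 fell in both, against 1.5 and 1.4 for independent lists.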

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

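The tests of library labels, of sex-linked genes and of LPS replicate 1 were chosen after the results were seen, and those of other splits of the libraries before.

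The LPS response by label differed between chow and Western diet libraries in 4291 genes. Of these, 686 changed sign in a fit with a lone library per Western diet arm, without the 4 libraries whose LPS-responsive genes go against their label. These are, of the 6 libraries labelled Western diet, replicates 1 and 3 labelled without LPS (slopes of 1.01 and 1.03 on the chow LPS changes) and replicates 1 and 2 labelled with LPS (-0.11 and -0.09). A diet effect shared by the 3 libraries of a label is argued against by slopes that range over 0.97 within a label. LPS labels exchanged among these 4 libraries may explain part of it, and an exchange as the whole account stays open. On 2630 genes without an LPS change in chow macrophages, replicate 2 labelled without LPS correlated at -0.48 with its label and 0.09 with its LPS state. Replicate 3 labelled with LPS correlated at -0.06 and -0.08 (differences of -0.57 and 0.02). Values were centred over the 6 libraries, which pulls correlations below 0, so only the differences are read. Replicate 2 labelled without LPS stood closer to its LPS state than to its label, and replicate 3 labelled with LPS about equally far from both. Gpnmb, Fabp5, Ctse, Chil3 and Mgst2 follow the label in all 6 libraries. They were taken from genes called by label, so this cannot weigh against an exchange. Of all genes tested, 14.2% lay apart by label, against 10% by chance. Why these genes follow the label stays open, as do diet and table.

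The 3 chow controls of the Western diet table follow a female pattern (Xist at 4.56, 3.55 and 7.72, the 4 Y-linked genes tested at 0), and the 6 libraries labelled Western diet a male one. All 9 libraries fit donors of different sex in the chow controls and the Western diet libraries, a candidate source of the 9 calls on chromosomes X and Y, and of an unknown part of the 15 elsewhere. The 12 libraries of the fatty acid table follow the male pattern. The labels name no sex, and diet and sex cannot be separated here.

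LPS replicate 1 of the fatty acid table lies farthest from the fatty acid libraries. That this library alone set the fatty acid calls is argued against by the 3100 of 3893 calls shared with a fit without it. A program that varies between LPS libraries and also moves with fatty acid may exist: the difference of a pair of LPS libraries correlated with the fatty acid change from the remaining library at -0.37, -0.48 and -0.23 across genes, and the smallest size, 0.23, is too low to decide.

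For the 6 comparisons of 3 against 3, the 10 splits of the libraries are too few for a share under 0.05. The real split was the only one of the 10 splits to give as many genes (1 of the 10 splits) for LPS in chow (6463, highest other 2), fatty acid (3893, highest other 3), TAK242 (491, highest other 1), fatty acid with TAK242 against LPS (617, highest other 2) and Western diet without LPS (24, highest other 2). For LPS by label in Western diet libraries 2 of the 10 splits gave as many genes; the split of replicate 2 labelled without LPS and replicates 1 and 2 labelled with LPS against the rest gave 5687 against 99, which points to a structure of the samples other than the labels. For the LPS response by diet, 3 of 100 drawn splits gave as many genes as the 4291 found (highest other 7058). These splits also break up the chow LPS groups, so the low share may come from the chow LPS effect, and an arbitrary grouping of the Western diet libraries stays open.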

How the results depend on the processing

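Median-ratio scaling, genes held fixed when libraries were left out, and leaving out 4 libraries were chosen after the data were seen. So were the replicate block and the pseudocount of 0.1 for the LPS response by diet, and leaving out each library for the correlations between comparisons. The other settings were chosen before. Values are genes changed at an adjusted p under 0.05, and the cause was not tested unless given.

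LPS in chow macrophages (6463) gave 4303 genes with the stricter filter, where fewer genes are tested, and fatty acid pretreatment (3893) stayed within 1.5 times throughout. TAK242 with fatty acid (491) gave 276 without a filter, 1110 with only the 6 libraries compared, 751 with median-ratio scaling, and 63 to 305 with a library left out. Fatty acid with TAK242 against LPS alone (617) gave 88 without a filter, 2 with only the 6 libraries, 1005 with scaling, and 1 to 1784 with a library left out. Western diet without LPS (24) gave 41 without a filter, 12 with the stricter filter, and 8 to 5838 with a library left out. LPS in Western diet macrophages (99) gave 58 with the stricter filter, 2 with only the 6 libraries, 210 with scaling, and 18 to 4086 with a library left out. The LPS response by diet (4291) gave 2731 with the stricter filter and 2142 to 6767 with a library left out.

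Without the 4 libraries whose LPS-responsive genes go against their label, Western diet without LPS gave 23 genes (12 higher and 11 lower, against 7 and 17, with 10 of the 24 calls kept), LPS in Western diet macrophages gave 3301 genes (863 higher and 2438 lower, against 70 and 29) and the LPS response by diet 1793 (868 higher and 925 lower, against 3217 and 1074), where 969 of the 4291 calls were kept and 686 changed sign. There LPS in chow against LPS in Western diet reversed from -0.723 to 0.664. Changes with LPS in Western diet macrophages also reversed in named genes not called in the main fit: Il1b went from -4.55 to 4.30, Nos2 from -4.004 to 3.42, Ccl5 from -4.47 to 8.88 and Stmn1 from 3.51 to -2.88. Fatty acid against Western diet went from 0.216 to 0.094. Without the 4 libraries a lone library was left per Western diet arm, so the spread in that table came from the chow controls alone. The lone libraries were assumed to vary like these controls. The gene counts of that fit are therefore listed for completeness and not read as numbers of changed genes. The 4 were chosen by LPS-responsive genes, so these values are no independent evidence. With only genes past the threshold, fatty acid against Western diet was 0.26 and fatty acid against the TAK242 change -0.883, by construction over larger changes.

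Of lists past the threshold, 18 with LPS in chow became 1 with an estimated correlation and 25 with fry. With fatty acid 11 became 0 and 16 with fry, and with TAK242 9 became 0 and 7 with fry. With fatty acid and TAK242 against LPS 14 became 0, also 0 with fry and 9 to 15 with a library left out. With Western diet 12 became 0 and 0 with fry, and with LPS in Western diet 15 became 0 and 6 with fry.

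Genes that did not pass turned direction with a library left out: S100a9 with LPS in chow ran from -0.16 to 1.20, and with fatty acid S100a9 ran from -0.77 to 0.60, Il10 from -0.17 to 0.14 (0.05 and 0.04 without fatty acid replicates 2 and 3), and Ccl2 from -0.69 to 0.20 (0.03 without LPS replicate 2).

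With the replicate number as a replicate block, LPS in chow gave 6364 genes, fatty acid 3716, TAK242 373, LPS in Western diet macrophages 0 and the LPS response by diet 3593. Same-number libraries of the fatty acid table showed little pairing. Their correlations ran from -0.01 to 0.06 with LPS in chow and from -0.01 to 0.2 with fatty acid with TAK242 against LPS. In both of these 2 of 3 libraries correlated best with their own number, against 1 with fatty acid and 0 with TAK242. With LPS in Western diet they ran from -0.67 to 0.76, but libraries of a label differ there in LPS state, so pairing cannot be judged. The genes held with each library left out, with genes fixed or with the filter applied again, were 5364 or 4901 for LPS in chow, 2470 or 2426 for fatty acid, 52 or 50 for TAK242, 1 or 1 for fatty acid with TAK242 against LPS, 8 or 1 for Western diet and 17 or 8 for LPS in Western diet. Count-only settings were not run because the tables hold no counts. Depth limits genes of low value, and 8803 to 10145 genes reached 1 per library.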

Other observations

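The lists and tests of this part were fixed before the results were seen, and the 3 matrix genes described were picked after.

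Of 17 genes of matrix remodelling, 8 rose and 4 fell with LPS in chow macrophages, 3 rose and 9 fell with fatty acid, and 4 rose and 3 fell with TAK242 (adjusted p = 0.176, 0.371 and 0.495 with an estimated correlation). Markers of stromal cells moved alongside, with 7 of 8 higher with LPS, 7 of 8 lower with fatty acid and 2 of 8 higher with TAK242 (adjusted p = 0.213, 0.371 and 0.698 with an estimated correlation), so the cell source stays open. The 3 genes below are the matrix members with an adjusted p among the 4 smallest in each of these comparisons, and they do not stand for the list. Mmp13, a collagenase gene, stood at 6.80 ± 0.278 untreated, 92.8 ± 23.8 with LPS, 20.3 ± 2.05 with fatty acid and 46.8 ± 7.93 with TAK242 added. The membrane protease gene Mmp14 stood at 4.25 ± 0.581, 157.3 ± 40.6, 47.3 ± 1.67 and 121.0 ± 16.2 in the same order. Timp2, an inhibitor of these proteases, ran the other way, at 24.6 ± 0.712, 2.63 ± 0.609, 10.7 ± 0.288 and 5.38 ± 0.530. For these 3 genes each step passed the threshold.

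With LPS in chow macrophages, NF-kB members and feedback inhibitors rose in 20 of 23 genes, MHC class II in 4 of 7, and lysosomal and lipid-associated macrophage genes fell in 17 of 23 (adjusted p = 0.0868, 0.262 and 0.262 with an estimated correlation). After median-ratio scaling the lysosomal count was 13. Costimulation genes split into 4 higher and 5 lower, with a median of -0.52 and a mean of 0.36, and the list did not pass (camera adjusted p = 0.177). Markers of stromal cells were the other cell type seen most in the fatty acid table, with a median over members of 8.38, each member taken in its own highest library.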
